A study of Homo sapiens with 6 samples.

How the data were processed

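Gene expression was measured in human primary fetal adrenal cells on an Illumina array with 24526 probes. The 6 samples fell into 3 labelled as untreated controls and 3 labelled as treated with ACTH, the pituitary hormone that drives the adrenal cortex, for 48 h. Per the labels, RNA was extracted with an RNeasy kit, checked on a Bioanalyser and turned into biotinylated cRNA, and GenomeStudio was named in the submitters' processing notes; its version, the scanner settings and any background subtraction are not given in the sources used here. The shared prefixes of the sample labels split the arrays into 2 runs, called array batch 1 (replicates 1 and 2 of each group) and array batch 2 (replicate 3 of each group). The labels number the samples of batch 1 only, and number 3 was assigned here to those of batch 2.

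The deposited table of probe intensity values was described by its header as not normalized. Its values were on a linear scale with no value near 0: the lowest signal was 86.4 to 88.5 on the batch 1 arrays and 144.2 to 145.6 on the batch 2 arrays. From the values, no background had been subtracted from them. The deposited detection p-value columns ran the other way from their name, with 1 for the brightest probes, and their rows were in another order than the signals (rank correlation with the signals between -0.0088 and -0.0047). Detection values were therefore paired with signals by rank within each array, since a detection value depends only on the rank of a signal against the negative controls. As a check, 96.0% of the 18196 rows of detection values with a value below 1 recurred in the paired table within 0.0034, against 35.6% for shuffled columns, and the largest difference was 0.0095. The authors' series table held log2 values: from the values, these equal log2 of the signals minus 1 constant per array, close to the log2 of its upper quartile, and minus each probe's median over the 6 samples. Its column medians were 0.039, -0.08 and 0.489 for control replicates 1 to 3 and -0.088, -0.13 and 0.519 for ACTH replicates 1 to 3. Scale, centring and direction were thus settled by the comparison with the signals. The signal rows carried array addresses without probe names, so they were matched to the named rows of the series table through their values. All 24526 rows matched one-to-one, with a largest distance of 3.5e-06 on the log2 scale and a smallest distance to the next candidate of 0.0088.

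Gene names came from the table of probe names given with the series and were checked through gene identifiers against a table of the GRCh38.p14 annotation, which changed 0 names. A single gene was named for 21834 probes, several for 0, and none for 2692; identifiers matched for 21813 probes. A gene without a named probe here is not analysed here. Before testing, 67 probes of sex-linked genes were left out, which left 24459. Of these, 15553 had a detection p under 0.05 in at least 3 of the 6 samples and were tested, and 8906 were not.

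Signals were background-corrected with the normal-exponential model of limma 3.58.1 (R 4.3.3), fitted from the detection p-values with an offset of 16, then quantile-normalized and put on the log2 scale. Groups were compared probe by probe with lmFit and eBayes, two-sided, without a block, and a probe was called changed at a Benjamini-Hochberg adjusted p under 0.05. For counts of genes, each gene was represented by its tested probe with the highest mean. The 22 gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, with an estimated correlation as the alternative, and p-values were adjusted over the lists. Where no array of a group detected a probe, the fold is given as a bound: the mean of the brighter group against the mean over the arrays of the dimmer group of the higher of the probe's own value and the lowest value among detected probes. It was computed with background correction and without it, and the lower bound of the 2 is the one reported first. The named genes followed a rule: the 12 largest rises and 12 largest falls among changed genes that moved the same way in all 3 same-numbered pairs of samples, up to 4 members of each list with the smallest unadjusted p, and STAR, CYP11A1, HSD3B2, CYP17A1, CYP21A2, CYP11B1, CYP11B2, SULT2A1, MC2R, MRAP, NR5A1, NR0B1 and NR4A1 where measured. Had fewer than 12 passed in a direction, the largest changes that did not pass would have filled the place. Other genes named in the text, such as FDX1, POR, SRD5A1, RRM2, PDGFA, GREM1, IFIT1, DDIT3 and ALB, were chosen after their values were seen. Groups, the tests between them, the 22 gene lists, the named-gene rule and all alternatives but 1 were fixed before the data were examined. The tests in the part on other observations, with their 2 gene lists, were set after the patterns they address had been seen.

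Alternatives covered the replicate number and the array batch as blocks, batch 1 alone, other background corrections and scalings, no filter and a stricter filter on dim probes, a variance trend with robust eBayes, the authors' log2 values, each sample and each replicate number left out, the mean over a gene's probes, 1 probe per gene tested alone, an adjusted p under 0.1, and fry. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The procedure was tested on simulated data made from the means and spreads of the 15553 tested probes, with 200 probes changed. Of 100 probes changed 2-fold, 47 were called, and of 100 changed 4-fold, 88 were called, with 2 calls among the 15353 unchanged probes. Far fewer probes were changed than the 1787 called in the data, and no shared difference between array batches was simulated. The shares called therefore need not hold for the data. In a simulation of 22 lists, the 1 list with 20 genes shifted by 1 on the log2 scale was called, and 0 unshifted lists were. The simulated data carried no correlation between genes. They therefore do not test the calls of lists with correlated genes, such as cholesterol synthesis (estimated correlation 0.363). The number of arrays limits the precision of all values. The labels do not say whether the 3 samples of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.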

Results

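The transcriptome of primary fetal adrenal cells was profiled after 48 h with ACTH and without treatment, with 3 samples per group. Median probe signals were 215.7 to 276.1 across the 6 arrays. Probes were detected at 62.2%, 64.1% and 55.3% in control replicates 1 to 3 and at 64.2%, 64.5% and 58.8% in ACTH replicates 1 to 3. The first principal component held 57.3% of the variance and separated the treatments, and the second held 23.8% and set the batch 2 arrays apart from those of batch 1. No arrays held identical values, and the closest pair, ACTH replicates 1 and 2, correlated at 0.993 across probes.

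The comparison asked which transcripts differed between ACTH-treated and untreated cells. By the brightest probe of each gene, 2 genes of cortisol synthesis had the largest fitted rises with background correction. HSD3B2, which makes the delta-4 steroids, rose 214-fold from a normalized log2 intensity of 5.37 ± 0.25 to 13.11 ± 0.59 (SD, n = 3). CYP21A2, the steroid 21-hydroxylase, rose 63.2-fold from 9.59 ± 0.31 to 15.57 ± 0.04 (SD, n = 3). HSD3B2 was detected in 1 of 3 controls, so its fold depended on the background: its log2 fold change was 7.74, compared with 6.42 at a background offset of 50, 5.75 without background correction and 5.71 with the authors' log2 values. For CYP21A2, detected in all 6 samples, it was 5.98, or 5.74 without background correction. The largest fitted fall was that of TECRL, whose log2 intensity fell by 4.81, or by 3.17 without background correction.

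Of 15553 tested probes, the limma fit gave 1787 probes changed by ACTH at the Benjamini-Hochberg threshold, 1025 higher and 762 lower. A change of at least 2-fold was found for 1007 of them, 658 higher and 349 lower. That count was 581 without background correction, 522 with the authors' log2 values, and 241 and 354 without both samples of replicates 1 and 2. By gene, 1452 of 11895 changed, 820 higher and 632 lower. With array batch as a block the count was 2812 probes, 1428 higher and 1384 lower, and included all 1787. Of the 1533 probes called in batch 1 alone, 1491 (97.3%) moved in the same direction between the 2 samples of batch 2. Of all 15553 tested probes, 72.4% did so. The log2 fold changes of the batches correlated at 0.739 across all tested probes, which are not independent replicates. The count of changed probes was 871 without control replicate 1, 763 without ACTH replicate 1, 1025 without ACTH replicate 2 and 976 without ACTH replicate 3. It was 241 without both samples of replicate 1, 354 without those of replicate 2 and 986 with the authors' log2 values. The fits with samples left out had no block. Without replicate 1 or 2 they kept 1 sample of each array batch per group, whereas leaving out replicate 3 kept batch 1 alone and gave 1533. Calls lost without replicate 1 or 2 therefore cannot tell dependence on those samples from the spread between batches. Of 119 changed genes that are named here or belong to a list, 12 to 38 no longer passed when a single sample was left out, most without ACTH replicate 1. Without both samples of replicate 1 this held for 70 of them, among them SOAT1, CNN1, RORA and CHAC1, and without those of replicate 2 for 67. Both times TIMP3, ZYX, STARD3, ASNS, IL6 and CD163 did not pass. With the authors' log2 values 18 did not pass: SRD5A1, PDE8A, FOSB, NR3C1, MAMLD1, STARD3, RRM2, TGFBR1, PDGFA, GREM1, MMP2, MYLK, PRRX1, TXN2, CYCS, GATA3, SLC7A11 and SESN2. Each of the 119 kept its direction. That says little about stability, since all 1787 changed probes moved the same way in both array batches before any sample was left out.

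**Figure D1:**
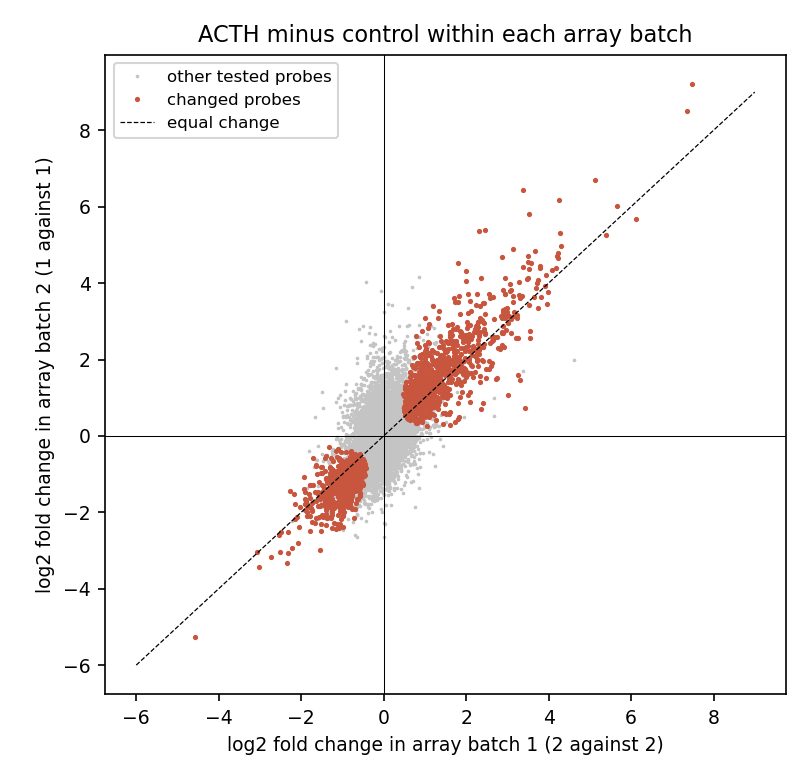
Log2 fold change (ACTH minus control) of each tested probe in array batch 1 (x axis, 2 samples against 2) and array batch 2 (y axis, 1 against 1), with the 1787 changed probes in colour and a dashed line of equal change. The changed probes were called from both batches together and lie in the quadrants where both have the same sign; 72.4% of all tested probes lie there.

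Beside the steroidogenic enzymes, the largest rises included genes of varied known roles. AMDHD1, an enzyme of histidine breakdown, rose by 5.79 ± 0.21 (SE) on the log2 scale, and NPTX1, a neuronal pentraxin, by 5.65 ± 0.38. NPTX1 was detected in 1 of 3 controls, and its second probe gave 1.54. GNRHR, the gonadotropin-releasing hormone receptor, rose by 5.35 ± 0.34 and SYP, a synaptic vesicle protein, by 4.52 ± 0.19. ELOVL3, a fatty acid elongase, and CD83, a surface protein of dendritic cells, each rose by 4.37, and VPREB3 by 4.40; ELOVL3 was detected in 2 of 3 controls and VPREB3 in 1. Without background correction the rises were 4.31 for AMDHD1, 3.88 for NPTX1, 4.52 for GNRHR, 3.44 for SYP, 2.73 for ELOVL3, 3.82 for CD83 and 2.74 for VPREB3. OPN4, NGEF and the chemokine CCL22 were detected in no control array and in all 3 ACTH arrays, and were at least 6.04-fold, at least 5.24-fold and at least 4.62-fold higher without background correction. With it the same bounds were 16.9, 14.6 and 12.2. The limma adjusted p of these genes ran from 4.67e-05 for CD83 to 0.00642 for VPREB3. The rule that named them admitted only genes that moved the same way in all 3 same-numbered pairs, as all 1787 changed probes did. VPREB3 and CCL22 did not pass without both samples of replicate 2 (limma adjusted p = 0.0634 and 0.0557).

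Among the 12 largest falls, TECRL changed by -4.81 ± 0.23 (SE, limma adjusted p = 0.000108), skeletal actin ACTA1 by -3.06 ± 0.30 and the small heat shock protein HSPB7 by -2.69 ± 0.25. HOPX, a homeodomain factor, changed by -3.16 ± 0.16, and the cell death regulator BMF by -2.88 ± 0.21. The potassium channel subunit KCNS1 changed by -2.57, the RNA polymerase III subunit POLR3F by -2.55 and ZNF385B by -2.32. The EGF receptor ligand HBEGF changed by -2.15 and the cell cycle inhibitor CDKN2B by -2.11. NKAIN4 and LRRC39 were detected in all 3 controls and in no ACTH array, and were at least 2.12-fold and at least 1.90-fold lower without background correction. With it the same bounds were 4.68 and 3.95. TECRL, BMF and POLR3F were each detected in 2 of 3 ACTH arrays. Without background correction the log2 fold changes were -3.17 for TECRL, -1.97 for ACTA1, -2.49 for HSPB7, -3.02 for HOPX, -1.70 for BMF, -2.17 for KCNS1, -1.45 for POLR3F, -1.55 for ZNF385B, -1.81 for HBEGF and -2.02 for CDKN2B. HBEGF and CDKN2B did not pass without both samples of replicate 1 (limma adjusted p = 0.0903 and 0.0686) or of replicate 2 (0.054 and 0.0671).

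Of 22 gene lists, camera in limma gave 8 gene lists shifted by ACTH, 5 higher and 3 lower, and with array batch as a block it gave the same number and directions. With an estimated correlation it gave 0 of 22, with 5 lists at an unadjusted p under 0.05, so each called list is given with both adjusted p-values. The estimated correlation was 0.004 for steroid synthesis and -0.042 for oxidative phosphorylation, below the preset 0.01. Their unadjusted camera p still rose from 4.08e-11 to 0.00237 and from 0.00154 to 0.0259. For these 2 lists a higher correlation between genes is therefore not the reason, and the reason was not tested. In the other called lists the estimate was 0.044 to 0.363.

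Steroid synthesis genes rose as a group. Of 14 tested members, 10 rose, 1 fell and 3 did not pass, with a mean log2 fold change of 2.51. STAR, which carries cholesterol into mitochondria, rose by 3.90 ± 0.34 (SE), CYP11A1, the side-chain cleavage enzyme, by 2.83 ± 0.14, and CYP11B1 by 3.42 ± 0.21. CYP17A1, which opens the way to cortisol and DHEA, rose from 9.38 ± 0.48 to 13.38 ± 0.17 (SD, n = 3). SULT2A1, the sulfotransferase that makes DHEA sulfate, rose by 1.80 ± 0.37, and the electron carriers FDX1 and POR rose by 3.32 and 2.17. SRD5A1 fell by 0.56. SULT2A1 did not pass without ACTH replicate 1 (limma adjusted p = 0.0815) or ACTH replicate 2 (0.0689), and SRD5A1 did not pass whichever of the 6 samples was left out, reaching 0.138 without ACTH replicate 1. Adjusted over the list alone, and also with array batch as a block, 10 rose and 2 fell, SRD5A1 and HSD17B1. Camera in limma gave an adjusted p of 4.49e-10, and the adjusted p = 0.0521 with an estimated correlation. The mean was 2.45 in batch 1 and 2.63 in batch 2. CYP11B2 and HSD3B1 did not pass the detection filter, each detected in no ACTH array. Binding of close copies to the probes of CYP21A2, CYP11B1 and HSD3B2 was not tested, and CYP11A1, SCARB1 and CYP21A2, at 15.94, 15.83 and 15.57 with ACTH, lay near the top of the scale.

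**Figure D2:**
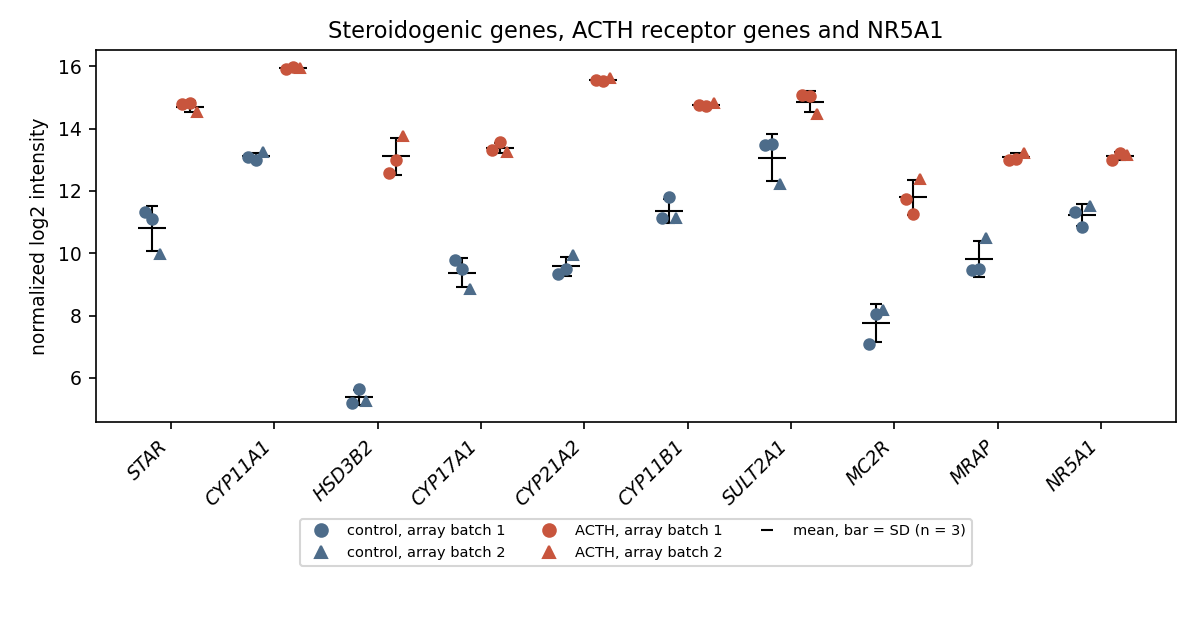
Normalized log2 intensity (y axis) of steroidogenic genes, ACTH receptor genes and NR5A1 in each sample, by group (colour) and array batch (symbol), with the mean and SD of 3 samples. Every ACTH sample lies above every control sample for each gene, from 5.37 to 13.11 on average for HSD3B2.

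The ACTH receptor MC2R rose by 4.03 ± 0.37 (SE) and its accessory protein MRAP by 3.28 ± 0.28 (limma adjusted p = 0.000877 and 0.000654). PDE8A, a cAMP phosphodiesterase, rose by 0.66, and RGS2 was at -0.65 without passing. Of 24 tested members of the receptor and cAMP list, 3 rose and 0 fell, also adjusted over the list alone. The fit with array batch as a block gave 3 rises and 2 falls, RGS2 and ADCY7. The list as a whole was not called (camera adjusted p = 0.806, mean 0.22, median -0.01). Among adrenal transcription factors, NR5A1, the master regulator of steroidogenic genes, rose by 1.90 ± 0.20 and RORA by 1.57, while NR3C1, the glucocorticoid receptor, fell by 0.81 and MAMLD1 by 0.55. Another called RORA probe fell by 0.55, and the second NR3C1 probe was at 0.23 without passing (limma adjusted p = 0.48). NR3C1 did not pass with the mean over its probes (-0.29, 0.223) or with the authors' log2 values (-0.48, 0.234). This list, with 2 up and 2 down of 12 in the fit without a block, adjusted over the list alone and with array batch as a block, was not called (camera adjusted p = 0.701). Its mean was 0.05, whereas its median was -0.28 and the test pointed down. The calls of PDE8A, MAMLD1 and NR3C1 ended without ACTH replicate 1 (limma adjusted p = 0.0959, 0.152 and 0.067) and ACTH replicate 2 (0.0831, 0.102 and 0.056), those of PDE8A and MAMLD1 also without control replicates 1 and 2 and ACTH replicate 3, and that of MAMLD1 without control replicate 3 too. NR0B1 had no probe named for it here.

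Cholesterol synthesis genes rose nearly throughout. Of 17 tested members, 15 rose and 0 fell, also adjusted over the list alone and with array batch as a block, with a mean log2 fold change of 1.87. MVD rose by 3.07 ± 0.24 (SE), EBP by 2.97 ± 0.25, NSDHL by 2.21 ± 0.17 and LSS by 2.13 ± 0.20. At the preset correlation camera gave an adjusted p of 6.53e-15, and the adjusted p = 0.153 with an estimated correlation. The mean was 1.65 in batch 1 and 2.29 in batch 2. In the cholesterol uptake and transport list, LIPE, which frees stored cholesterol, rose by 3.45 ± 0.20, SOAT1 by 2.10 and STARD3 by 1.51. STARD3 was at 0.92 without background correction and at 0.91 with the authors' values, where it did not pass (limma adjusted p = 0.0535). The HDL receptor SCARB1 rose from 12.87 ± 0.34 to 15.83 ± 0.13 (SD, n = 3), near the top of the scale. Of 19 tested members, 5 rose and 2 fell (6 and 4 adjusted over the list alone, 6 and 3 with array batch as a block), and the list was not called (camera adjusted p = 0.054). It was called in 7 of 24 other settings, among them a background offset of 50 (0.0457), trend and robust eBayes (0.0436) and without replicate 1 (0.0246).

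Actin cytoskeleton genes fell as a group. Of 21 tested members, 8 fell and 0 rose (10 fell adjusted over the list alone), with a mean of -0.59. Some brightest probes, such as those of ACTA2 (15.88 to 15.99) and TAGLN (15.62 to 15.94), lay near the top of the scale, where a fall may not show. TAGLN was at 0.03 by that probe and at -1.075 and -0.519 by others, without passing (limma adjusted p = 0.0602 and 0.0531). A dimmer TPM2 probe fell by 0.68 (0.0243), while other probes of TPM2 and ACTB were at -0.34 and -0.08 without passing. CNN1, a smooth muscle calponin, changed by -1.61 ± 0.24 (SE), the focal adhesion protein ZYX by -1.02 ± 0.16, the transcription factor SRF by -0.77 ± 0.14 and CCN1 by -0.92 ± 0.17. The list had a camera adjusted p of 5.11e-05, and the adjusted p = 0.153 with an estimated correlation. SRF and CCN1 did not pass without ACTH replicate 1 (limma adjusted p = 0.0663 and 0.0624) or ACTH replicate 2 (0.0537 and 0.0541), nor SRF without control replicate 1 (0.0573). The mean was -0.52 in batch 1 and -0.73 in batch 2. In the extracellular matrix list, of 29 tested, 4 fell and 0 rose (5 fell adjusted over the list alone), with a mean of -0.37, -0.39 in batch 1 and -0.33 in batch 2. TIMP3 changed by -1.16 ± 0.15, COL8A1 by -0.67, LOX by -0.61 and MMP2 by -0.77. COL1A1 lay near the top of the scale in every sample (15.95 to 16). For the matrix list camera gave an adjusted p of 0.000337, and the adjusted p = 0.17 with an estimated correlation. COL8A1 and MMP2 lost their calls whichever sample was left out, with limma adjusted p-values of up to 0.103 and 0.135, and LOX lost its call whichever sample other than control replicate 3 was left out, with up to 0.12. The second COL8A1 probe was at -0.59 without passing (limma adjusted p = 0.0946). Beside both lists, 1 of 12 fibroblast and stromal markers fell, PRRX1 by 0.63, and 0 did adjusted over the list alone. That list was not called (camera adjusted p = 0.235, or 0.117 with array batch as a block). With that block 5 of the 12 fell, PRRX1, TWIST1, FAP, THY1 and S100A4, and 1 rose, OGN, beside 10 actin and 7 matrix genes that fell. PRRX1 did not pass whichever sample was left out, with an adjusted p of up to 0.139, and its second probe was at -0.04.

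The unfolded protein response list shifted down (mean -0.40, -0.33 in batch 1 and -0.54 in batch 2). The members that fell were CHAC1 (-1.44), TRIB3 (-1.40), ASNS (-1.07) and DDIT3 (-1.04), which also answer amino acid shortage, and DNAJB9, a chaperone partner, rose by 1.03. A second ASNS probe was at -0.64 without passing (limma adjusted p = 0.17). Adjusted over the list alone 1 rose and 6 fell of 17, and with array batch as a block 1 and 5, PDIA4 being the added fall. The camera adjusted p was 0.0256, and the adjusted p = 0.369 with an estimated correlation; it was 0.07 in batch 1 alone and 0.0893 without control replicate 3. DDIT3 did not pass without control replicate 1, ACTH replicate 1 or ACTH replicate 3 (limma adjusted p = 0.0748, 0.0771 and 0.0512). Oxidative phosphorylation genes shifted up by a mean of 0.23 (0.20 and 0.30 in batches 1 and 2), with 1 of 20, CYCS, past the threshold at 0.74, also with array batch as a block, and 0 adjusted over the list alone. CYCS, the electron carrier cytochrome c, did not pass whichever sample was left out, with a limma adjusted p of up to 0.107. SDHA and NDUFV2 were at 0.42 and 0.41 without passing. This list had a camera adjusted p of 0.00678, and the adjusted p = 0.153 with an estimated correlation.

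Oxidant defence genes shifted up by a mean of 0.42 (0.38 and 0.49 in batches 1 and 2) and a median of 0.15, as 1 gene, GSTA1, was far above the others. The 4 of 20 that rose were GSTA1, a glutathione transferase with close copies, by 3.79 ± 0.27 (SE), GPX3 by 1.15, TXN2 by 0.87 and SRXN1 by 0.75, with 5 adjusted over the list alone and 7 with array batch as a block. Leaving out ACTH replicate 1, 2 or 3 ended the calls of GPX3 (limma adjusted p up to 0.064), TXN2 (up to 0.0901) and SRXN1 (up to 0.103); that of TXN2 also ended without control replicate 1, and that of SRXN1 without each control. TXN2 was at 0.33 without background correction (0.0862) and at 0.26 with the authors' log2 values (0.744). Camera in limma gave the list an adjusted p of 0.0395, and the adjusted p = 0.386 with an estimated correlation. Without control replicate 3 it was 0.138, and without ACTH replicate 2 it was 0.0649. In batch 1 alone it was 0.07. It was 0.0553 without background correction, with a mean of 0.34, and 0.0915 with the authors' values, with a mean of 0.32. Chromaffin and sympathoadrenal markers shifted up by a mean of 0.47 (0.57 and 0.27 in batches 1 and 2), with 1 of 10, GATA3, past the threshold at 0.99 and 2 adjusted over the list alone. With array batch as a block 4 rose, GATA3, CHGA, ELAVL4 and DBH (camera adjusted p = 0.00374). In the fit without a block CHGA, a granule protein, was at 0.57, ELAVL4 at 0.78 and DDC at 0.44 without passing. GATA3 did not pass whichever sample other than control replicate 3 was left out, with an adjusted p of up to 0.0904. It was at 0.42 without background correction (0.051) and at 0.39 with the authors' log2 values (0.573). For this list the camera adjusted p was 0.0325, and the adjusted p = 0.378 with an estimated correlation. In both batch 2 samples, 1 of these 10 markers was above and 4 were below every batch 1 sample, compared with 8.58% and 10.2% of all tested probes. The adjusted p was 0.0619 without control replicate 3, 0.122 without ACTH replicate 1 and 0.0649 without ACTH replicate 2. Without background correction the mean was 0.24 (0.0553), with the authors' values 0.22 (0.0915) and with probes detected in all 6 samples 0.34 (0.387).

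**Figure D3:**
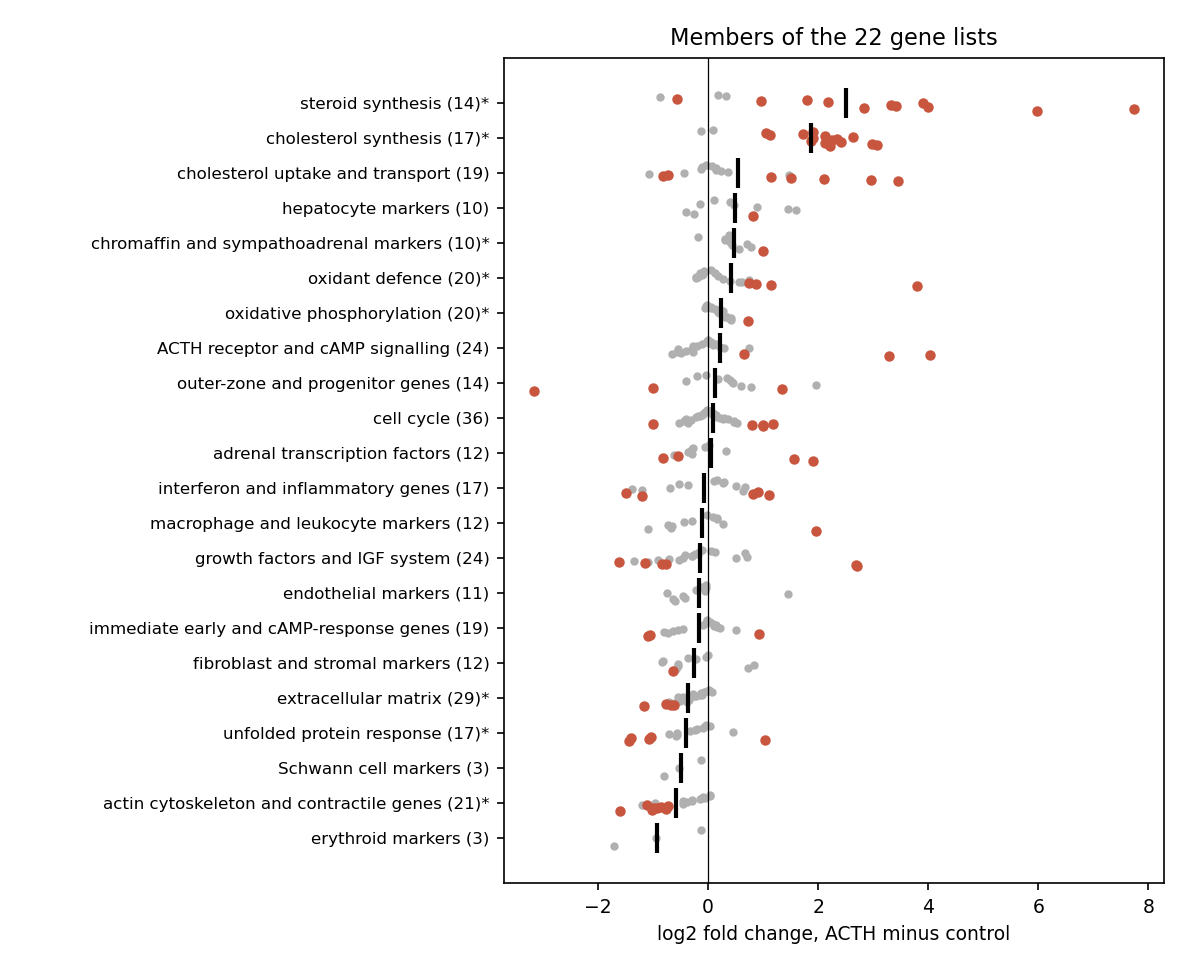
Log2 fold change (x axis, ACTH minus control) of the tested members of the 22 gene lists, with changed genes in colour, other genes in grey, the list mean as a bar and the number tested in parentheses; an asterisk marks the 8 lists called by camera at the preset correlation. Steroid synthesis and cholesterol synthesis have the highest means, 2.51 and 1.87.

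Other lists held changed genes without a call for the list. Growth factor genes INHA and IGF2 rose by 2.70 ± 0.18 (SE) and 2.69 ± 0.32, and TGFBR1, EGFR, PDGFA and GREM1 fell, by 0.84, 0.76, 1.15 and 1.63. That is 2 up and 4 down of 24, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.149). The batch block gave 4 and 6, with ANGPT1 and ANGPT2 added up and FGF2 and TGFB2 down. Without background correction TGFBR1 was at -0.33 (limma adjusted p = 0.0629) and PDGFA at -0.49 (0.0363). With the authors' values TGFBR1, PDGFA and GREM1 were at -0.38, -0.55 and -1.28 and did not pass (0.525, 0.353 and 0.0564). IGF2 passed in both settings, at the smaller rises of 1.915 and 1.874. TGFBR1 and EGFR did not pass without ACTH replicate 1 (limma adjusted p = 0.0695 and 0.0609), nor EGFR without ACTH replicate 2 (0.0562). The second EGFR probe was at -0.55 without passing (limma adjusted p = 0.145). The call of PDGFA ended without control replicates 1 and 2 and ACTH replicate 3 (up to 0.0862), and that of GREM1 without control replicate 1 and each ACTH replicate (up to 0.0923).

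Among immediate early genes at 48 h, FOSB and EGR1 fell by 1.08 and 1.05 and SIK1 rose by 0.93, 1 up and 2 down of 19, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.5). Under the batch block 1 rose and 4 fell, ATF3 and IER2 being added. ATF3 was at -0.73 without passing (limma adjusted p = 0.0592), which ranged from 0.0213 to 0.423 in the other settings. FOSB was at -0.66 without background correction and at -0.67 with the authors' values, where it did not pass (0.0935). EGR1 did not pass without ACTH replicate 2 (limma adjusted p = 0.0534), and SIK1 did not pass whichever ACTH replicate was left out (up to 0.0743). NR4A1 was detected in no sample. Of 36 cell cycle genes, 4 rose and 1 fell, also over the list alone: AURKA, CCNE1, CDK1 and RRM2 rose by 1.00, 1.01, 0.79 and 1.18, and TK1 fell by 1.00 (camera adjusted p = 0.338). RRM1 was added as a rise with array batch as a block. The calls of CDK1 and RRM2 ended without control replicate 1 and without each ACTH replicate (limma adjusted p up to 0.0835 and 0.118), and that of TK1 whichever sample other than control replicate 2 was left out (up to 0.0995). Of 17 interferon and inflammatory genes, IFI44L, IFIT3 and IFIT1 rose by 1.11, 0.82 and 0.91, and IL6 and CCL2 fell by 1.20 and 1.49. Adjusted over the list alone 6 rose and 5 fell, and with array batch as a block 3 and 4, IL1B and IL1A being added (camera adjusted p = 0.576). Other IFIT3 probes were at 1.60 and -0.03. Its mean was -0.08, whereas its median was 0.15 and the test pointed up. Without ACTH replicate 1 IFIT3, IFIT1 and CCL2 did not pass (limma adjusted p = 0.0575, 0.0984 and 0.0783); IFIT1 also lost its call without each control and ACTH replicate 3 (up to 0.101), and CCL2 without control replicates 1 and 2 (0.099 and 0.0724). In the outer-zone and progenitor list, RSPO3 rose by 1.35 and HOPX and NCAM1 fell, by 3.16 and 1.00, with 1 up and 2 down of 14, 4 and 2 adjusted over the list alone, or 2 and 2 with array batch as a block (camera adjusted p = 0.338). AXIN2 was at 0.77 without passing, and passed with that block. DLK1 was counted as not passed by its brightest probe, which lay near the top of the scale in all samples (15.81 and 15.99 on average); its other probe rose by 1.72 (limma adjusted p = 0.000922). RSPO3 did not pass without control replicate 1 or 2 or ACTH replicate 1 or 3 (up to 0.06), and NCAM1 lost its call whichever sample other than ACTH replicate 3 was left out (up to 0.102). The second NCAM1 probe was at -0.54 without passing (limma adjusted p = 0.335). With the mean over its probes NCAM1 was at -0.77 and did not pass (0.0923).

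Markers of other cell types were examined in the same samples. CD163, a macrophage receptor, rose by 1.97 ± 0.33 (SE), alone among 12 tested macrophage and leukocyte markers, also adjusted over the list alone (camera adjusted p = 0.662). Without both samples of replicate 1 or 2 it did not pass (limma adjusted p = 0.13 and 0.0797). APOA1, an apolipoprotein, rose by 0.81, alone among 10 tested hepatocyte markers, also adjusted over the list alone (camera adjusted p = 0.538). APOA1 did not pass without control replicate 1 or 2 or ACTH replicate 1 or 2, with a limma adjusted p of up to 0.0738. With array batch as a block 4 hepatocyte markers rose, APOA1, TF, ALB and APOA2 (camera adjusted p = 0.0639). Of 11 endothelial, 3 Schwann and 3 erythroid markers, 0 changed, with camera adjusted p-values of 0.423, 0.235 and 0.423; adjusted over the list alone 1 Schwann marker, GFRA3 at -0.80, was past the threshold. LAPTM5, ENG and HBA2 were at -1.08, -0.59 and -1.70 without passing. The same block called the endothelial markers VWF, higher, and EMCN and ESAM, lower, the macrophage marker TYROBP, lower, and HBA2, lower (limma adjusted p = 0.000798), and 0 Schwann markers. The batch 2 samples stood apart in several of these lists, in both groups. ALB was at 10.61 in the batch 2 control and 12.46 in the batch 2 ACTH sample, against 5.74 to 7.61 in batch 1. Above every batch 1 sample in both batch 2 samples were 9 of 11 endothelial and 6 of 10 hepatocyte markers, compared with 8.58% of all tested probes, and 3 of 3 erythroid markers were below, compared with 10.2% of all tested probes.

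**Figure D4:**
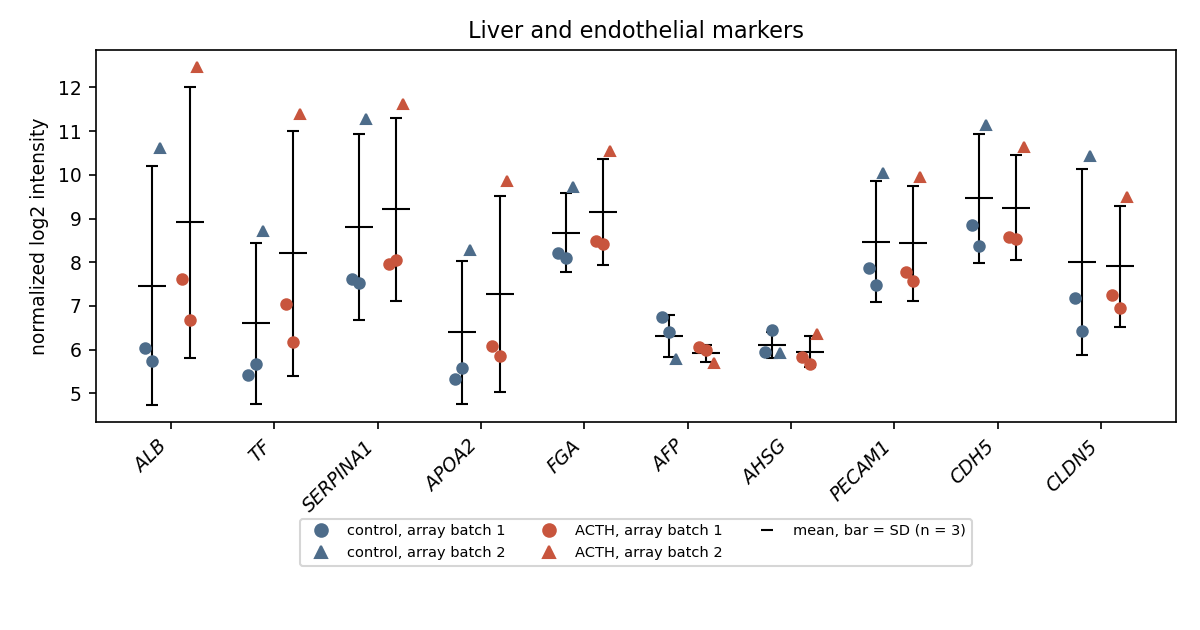
Normalized log2 intensity (y axis) of liver and endothelial marker genes in each sample, by group (colour) and array batch (symbol), with the mean and SD of 3 samples. ALB lies at 10.61 and 12.46 in the batch 2 samples and at 5.74 to 7.61 in batch 1, whereas AFP is not higher in batch 2.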

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

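The crossed pairing of batch 1 samples was the only setting chosen after the data were seen. The count of changed probes was 2812 with array batch as a block, which takes the difference between batches out of the residual spread. It was 2790 at an adjusted p under 0.1, the same fit at a looser threshold. With 1 sample or 1 replicate number left out it was 241 to 1622, and those counts rest in part on fewer samples. It was 986 with the authors' log2 values and 2902 with the crossed pairing, and the cause of these differences was not tested. In the remaining settings the count was 1533 to 2128, and all probes shared with the reported calls kept their direction. Camera with an estimated correlation gave 0 gene lists, and the other settings gave 6 to 10. Batch 1 alone and the setting without replicate 3 are the same fit; counting it once, the calls of the chromaffin, oxidant defence and unfolded protein response lists were lost in 10, 9 and 3 settings. Calls were gained by the cholesterol uptake list in 7 of 24 settings (adjusted p 0.00197 to 0.248), by hepatocyte markers with the replicate number as a block (0.0455, against 0.0639 to 0.772 elsewhere) and by erythroid markers in batch 1 alone (0.0241) and without control replicate 3 (0.0499, and up to 0.763 elsewhere), and with fry also by immediate early genes (0.0263) and growth factors (0.0084). All 1787 changed probes had moved the same way in both array batches, which left called genes little room to change sign. No called gene or list changed sign in any setting. Among those not called, the mean of macrophage and leukocyte markers turned to 0.182 in batch 1 alone, and SOX10 to 0.108. With samples left out, the values ran from -0.338 to 0.182 for macrophage and leukocyte markers, -0.573 to 0.394 for endothelial markers, -0.248 to 1.019 for hepatocyte markers, -0.139 to 0.007 for interferon and inflammatory genes, -0.016 to 0.113 for adrenal transcription factors, -0.408 to 0.202 for SOX10 and -0.414 to 0.192 for HBG1. The replicate numbers were checked for pairing. Same-numbered samples deviated from their group means with correlations across probes of 0.237, -0.212 and 0.425. The last value is for the batch 2 samples, whose labels carry no number. It cannot tell a pair from a shared array batch. Control replicate 1 correlated best with ACTH replicate 2 (0.492), so the numbers were not borne out as pairs. The fit without a block had been fixed before this check. As a block the numbers gave 1855 probes, and the named-gene rule used them as same-numbered pairs. Of the 10 splits of the 6 samples into groups of 3, 1 gave as many limma calls, the real one with 1787; the highest other gave 0 (67 to 1350 at an unadjusted p under 0.05), and 10 splits cannot give a share under 0.1. Dim probes limit what can be called: 8906 were not tested for lack of signal over background.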

Other observations

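The tests on chaperones, stromal markers, liver markers and MOB4 probes were chosen only after the result was seen. The genes named in this part were chosen after their values were seen.

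Fatty acid synthesis genes rose beside the cholesterol genes. Of 15 tested genes outside the fixed lists, 10 rose and 0 fell, and 14 rose adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, rose by 2.47, the desaturase FADS1 by 1.58, LPIN1 by 1.46 and fatty acid synthase FASN by 1.19. The median log2 fold change was 0.857, with 0.71 in batch 1 and 1.24 in batch 2. The hypothesis that the sterol response extended to fatty acid synthesis predicted a median of at least 0.3, so this value is consistent with it. For camera in limma, adjusted over the 2 lists tested in this way, the adjusted p was 1.19e-10. With an estimated correlation, the camera adjusted p = 0.0474. Both lists were set after the patterns had been seen, and the fixed lists were adjusted over more lists, so the adjusted values are not comparable. With an estimated correlation the unadjusted camera p was 0.0474 here, against 0.00237 for steroid synthesis, whose adjusted p was 0.0521. Passing here therefore does not set this list above the fixed ones. LPIN1 did not pass without control replicate 1 or ACTH replicate 1 (limma adjusted p = 0.0805 and 0.0663).

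Genes that answer amino acid shortage fell together outside the fixed lists. Of 28 tested targets, 13 fell and 0 rose, and 19 fell adjusted over the list alone. GDF15 changed by -1.57, the cystine transporter SLC7A11 by -1.41, the amino acid transporter SLC7A5 by -1.15, SESN2 by -1.14 and PCK2 by -1.07. The median was -0.665, with -0.60 in batch 1 and -0.77 in batch 2, which met the bound of -0.3 predicted for a lower amino acid response. The test followed the fall already seen in ASNS, TRIB3, CHAC1 and DDIT3, genes of the unfolded protein response list. It therefore cannot tell a lower amino acid response from lower endoplasmic reticulum stress. The camera adjusted p over the same 2 lists was 4.36e-09, and adjusted p = 0.0474 with an estimated correlation (unadjusted camera p = 0.0288). These values are likewise not comparable with the adjusted p-values of the fixed lists. SESN2 did not pass without control replicate 1, ACTH replicate 1 or ACTH replicate 3 (limma adjusted p up to 0.0707). With the authors' log2 values SLC7A11 and SESN2 were at -0.76 and -0.79 and did not pass (0.0629 and 0.0531), and without background correction SLC7A11 was at -0.74. Lower endoplasmic reticulum stress as a whole stayed open. The 10 chaperones of the unfolded protein response list had a median of -0.222 (bootstrap SE 0.192), above the bound of -0.618. The gap of 0.396 was over 2 bootstrap SE but less than the SD of 0.542 between the chaperones, a limit added after the result was seen. The bound was set from the median of ASNS, TRIB3, CHAC1 and DDIT3, the members called as fallen in the same data, so it was not independent of them. DNAJB9 rose by 1.03 and PDIA6 was at 0.45 without passing, each with an interval wholly above 0, whereas CALR, HSPA5, PDIA4 and HYOU1 were at -0.71, -0.58, -0.56 and -0.55, with intervals wholly below 0 but without passing (limma adjusted p = 0.123, 0.101, 0.109 and 0.134). PDIA4 passed with array batch as a block (0.0472). What lowered these genes was not tested.

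The fall of actin and matrix genes may have come from fewer stromal cells in the ACTH cultures, which would lower all stromal markers alike. Of 12 tested stromal markers, 2 had a 95% interval wholly above 0: PDGFRA at 0.72 (0.20 to 1.24) and OGN at 0.84 (0.13 to 1.56), although these intervals are not adjusted over the 12 markers and neither probe passed in limma (adjusted p = 0.0848 and 0.129). The second OGN probe rose by 0.88 (limma adjusted p = 0.0351). By contrast, the intervals of TWIST1 (-0.98 to -0.17), PRRX1 (-1.02 to -0.25) and FAP (-0.97 to -0.12) lay wholly below 0. The median of the 12 markers was -0.455. With array batch as a block OGN rose (limma adjusted p = 0.0307), PDGFRA did not pass (0.0706), and PRRX1, TWIST1, FAP, THY1 and S100A4 fell. The 2 intervals above 0 met the bound of at least 2 set against a loss of all stromal cells alike. Since ACTH could have raised those markers in the cells themselves, the test does not decide it. Fewer stromal cells, a change in 1 kind of stromal cell and an effect of ACTH on the cells themselves all stay open.

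Liver markers were high in both batch 2 samples, and liver cells in those cultures are a candidate source. Of 10 tested markers, 6 were higher in both batch 2 samples than in every batch 1 sample, between the bounds of at least 7 for liver cells and fewer than 4 against them, so the test did not decide; TTR, untested because too few samples detected it, was also higher (7.95 and 7.15 against 5.46 to 5.59). TF was at 8.72 and 11.40 in batch 2 and at 5.43 to 7.04 in batch 1, whereas AFP, abundant in fetal liver, was at 5.79 and 5.69, and AHSG, APOA1 and VTN were not higher either. 0 of the markers are in another list used here, and how many of them fetal adrenal cells express was not tested. Endothelial markers were high in the same samples (CDH5 at 11.14 and 10.63 against 8.38 to 8.86), and a difference in tissue, culture or array run stays open as well.

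MOB4 probes rose unequally. Of 3 tested probes, 2 rose at least 2-fold, by 8.06 and 2.61, and the other was at 0.45 (limma adjusted p = 0.259). A single probe that picks up another transcript as the cause stays open, since the probe sequences were not available and 1 probe carries most of the rise.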
